A study of Equus caballus with 16 samples.

How the data were processed

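Messenger RNA was measured by sequencing in 16 libraries of equine tenocytes, the resident cells of tendon. Per the labels' protocols, cells were grown in serum-containing medium and stable lines were made with a plasmid vector carrying a short hairpin RNA (shRNA) designed against human SCX or a scrambled non-target (NT) hairpin. Libraries were prepared from total RNA with a stranded mRNA kit, and paired reads of 100 bases were collected. The labels describe 1 shSCX sequence and 1 NT sequence, so every comparison of shSCX with NT is between these sequences. Samples were grouped by stage and hairpin from the titles and the cell type label, which gave 4 groups of 4 libraries. The line named in the title was the replicate, and the series design calls the lines independent.

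The authors deposited estimated counts per gene, with adult and fetal libraries in separate tables over the same 21689 horse Ensembl gene identifiers. FastQC, Salmon and R 3.5.2 are named in the submitters' processing notes. The transcript set, genome build and the step from transcripts to genes are not given in the sources used here. The deposited values were not scaled: column totals differed, and between 94.6% and 95.8% of the values of a library were whole within 0.01. Salmon shares reads between similar transcripts, so values of near-identical gene copies are uncertain. The estimated counts were rounded to whole numbers before any count test. Because both tables held unscaled counts of the same identifiers, adult and fetal libraries were also fitted together.

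The deposited tables do not pair identifiers with symbols, and 0 of the 21689 identifiers matched the gene table used here (assembly TB-T2T). The level of SCX, the 33 gene lists and the cell type markers that were fixed before the data were examined were therefore not analysed here, and the knockdown itself was not checked. Genes are given by identifier, at most 2 per direction and comparison. The rule for these genes, fixed before the data were examined, took those with the largest change among genes at adjusted p under 0.05 with the same sign in all 4 lines (for the stages, no overlap between groups) and a mean of at least 50 normalised counts in the higher group. The part of that rule asking for a symbol was dropped. For the interaction the sign condition was replaced by no overlap of the log2 ratios between adult and fetal lines. Where fewer genes met the rule, genes meeting its sign or overlap condition were taken by smallest unadjusted p. They are given as not past the threshold. As fixed, the rule named more genes per direction and turned to unadjusted p below a larger number of genes. Both numbers were reduced to 2 here. A pair of table columns bore the prefix TB without a number and was assigned to line TB171012 because the titles of the other adult lines were all taken.

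Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). The shSCX effect was fitted within adult and within fetal libraries, each with the line as a block, since both libraries of a pair came from the same line. As a check of the pairing, deviations from the group means were correlated, and r within pairs ran from 0.41 to 0.831. For 8 of 8 lines the shSCX library correlated best with its own NT library. Only NT libraries of the same stage were compared, so a swap between stages was not checked. Centring on group means also lowers the correlations between different lines. The difference between the fetal and adult shSCX effects was tested as an interaction in all 16 libraries, and fetal were compared with adult NT libraries without a block. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Normalised counts are TMM-scaled counts at the geometric mean library size, and log2 ratios per line used a prior count of 2. A fit of 1 shSCX effect over all 8 lines, a response score per line and the change of the most abundant genes were added after seeing the data.

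Libraries held between 17628158 and 26157162 counts. No 2 columns were identical, and libraries of one group differed by at least 43.3 times the sampling noise (chi-square per degree of freedom over genes with a summed count of 20 or more), so each counted as 1 replicate. Simulated counts with 50 genes changed at each fold size were tested first. At 2-fold, 80% of changed genes were recovered in the adult design among 12513 simulated genes, 84% in the fetal design among 12418, 42% for the interaction among 12888, 12% between stages among 12384 and 86% over 8 lines among 12888. At 4-fold these shares were 94%, 96%, 82%, 84% and 100%. False calls made up 8.09% of simulated calls in the adult design, 8.47% in the fetal design, 6.03% for the interaction, 4.11% between stages and 4.95% over 8 lines.

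Alternatives were DESeq2 1.42.0 size factors and Wald test, limma 3.58.1 voom, no filter on low counts, a filter of 1 CPM in every library of a group, an adjusted p of 0.10, a fold of at least 2, no replicate block, all 16 libraries in one fit, passage or 1 surrogate variable (sva 3.50.0) as a covariate between stages, and each line left out in turn. Intervals of count ratios are exact binomial at 95% and cover counting error only. Comparisons of single values between the 4 adult and 4 fetal lines used two-sided exact permutation tests over 70 labelings.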

Results

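Gene expression was measured in cultured equine tenocytes from 4 adult lines (horses of 2 to 10 years) and 4 fetal lines named by gestation day (271, 316, 319 and 320 days). Each line was sequenced once with a non-target (NT) short hairpin RNA and once with a hairpin against SCX (shSCX), which encodes Scleraxis, a transcription factor of tendon cells. The cells were at passages 5 to 8. The series asks whether Scleraxis regulates different genes at the 2 developmental stages. Total counts ran from 20865437 to 26157162 in the 8 adult libraries and from 17628158 to 23148025 in the 8 fetal libraries. Between 12185 and 12692 genes per library had 10 or more counts, and the 10 most abundant genes took 15.9% ± 1.99 of the counts (SD, n = 16). The level of SCX was not analysed here, because the identifiers carried no symbols, so shSCX and NT are the labels of the libraries.

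In adult tenocytes 325 of 12513 genes changed with shSCX, of which 242 rose and 83 fell. Among called genes with a mean of at least 50 normalised counts in the higher group, ENSECAG00000000750 had the largest rise, with a fitted within-line log2 fold change of 4.67 (SE 0.42, edgeR adjusted p = 0.00496), or 25.5-fold. Its log2 ratios per line averaged 3.73 ± 1.54 (SD, n = 4), below the fitted value, which was 3.68 without TB171012. Its group means, which the lines with the highest counts dominate, were 43.8 ± 56.1 normalised counts with NT and 1717 ± 2933 with shSCX (SD, n = 4). ENSECAG00000017826 rose from 15.8 ± 12.3 to 128 ± 105 normalised counts (SD, n = 4), a log2 fold change of 2.99 (SE 0.38, edgeR adjusted p = 0.0107), or 3.57 without TB171012. Above the same minimum of counts, the genes that fell furthest were ENSECAG00000023039, with a log2 fold change of -2.79 (SE 0.37, edgeR adjusted p = 0.0119), and ENSECAG00000012645, which went from 85.8 ± 11.5 to 18.96 ± 6.50 normalised counts (SD, n = 4; log2 fold change -2.20, SE 0.27, edgeR adjusted p = 0.00872). Each of these 4 genes moved the same way in 4 of 4 adult lines, which the naming rule required. All 325 called genes did so too, which a paired test of 4 lines favours.

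Of the adult calls, 117 changed at least 2-fold, 88 upward and 29 downward, and the median size of a called change was 0.85 on the log2 scale. Before adjustment 2189 genes were at p under 0.05, where 626 would be expected by chance. With a line left out there were 1356 (without S) to 2393 (without TB130911). Of the tested genes 26.3% had the same sign in all 4 lines, where chance gives 12.5%. The result rested on the paired design: without the line as a block 1 gene was called, and none of the 4 named genes passed. The count fell to 27 without line S, 92 without TB171012 and 160 without TB130911, and was 709 with the DESeq2 Wald test and 508 with all 16 libraries in one fit. ENSECAG00000017826 lost its call without TB180412 (adjusted p = 0.05003) or S (0.0653), ENSECAG00000023039 without S (0.0713), and ENSECAG00000012645 without TB171012 (0.0548) or S (0.0711), all with edgeR.

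In fetal tenocytes 2138 of 12418 genes changed with shSCX, 1140 upward and 998 downward. Above the same minimum of counts, ENSECAG00000000750 again had the largest rise, with a fitted within-line log2 fold change of 5.64 (SE 0.47, edgeR adjusted p = 0.00206) and group means of 62.9 ± 98.7 normalised counts with NT and 2224 ± 1795 with shSCX (SD, n = 4). ENSECAG00000016559 rose from 8.01 ± 7.16 to 317 ± 103 normalised counts (SD, n = 4; log2 fold change 5.31, SE 0.37, edgeR adjusted p = 0.00138). Without 319d the fitted values of these genes were 6.70 and 5.996. ENSECAG00000009723 fell from 145 ± 118 to 18.02 ± 16.4 normalised counts (SD, n = 4; log2 fold change -2.96, SE 0.28, edgeR adjusted p = 0.00271). ENSECAG00000006249 fell from 133 ± 63.0 to 21.4 ± 15.3 (SD, n = 4; log2 fold change -2.72, SE 0.32, edgeR adjusted p = 0.00464). All 4 moved the same way in 4 of 4 fetal lines, which the naming rule required. Of the 2138 called genes 2130 did so, which a paired test of 4 lines favours.

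**Figure D1:**
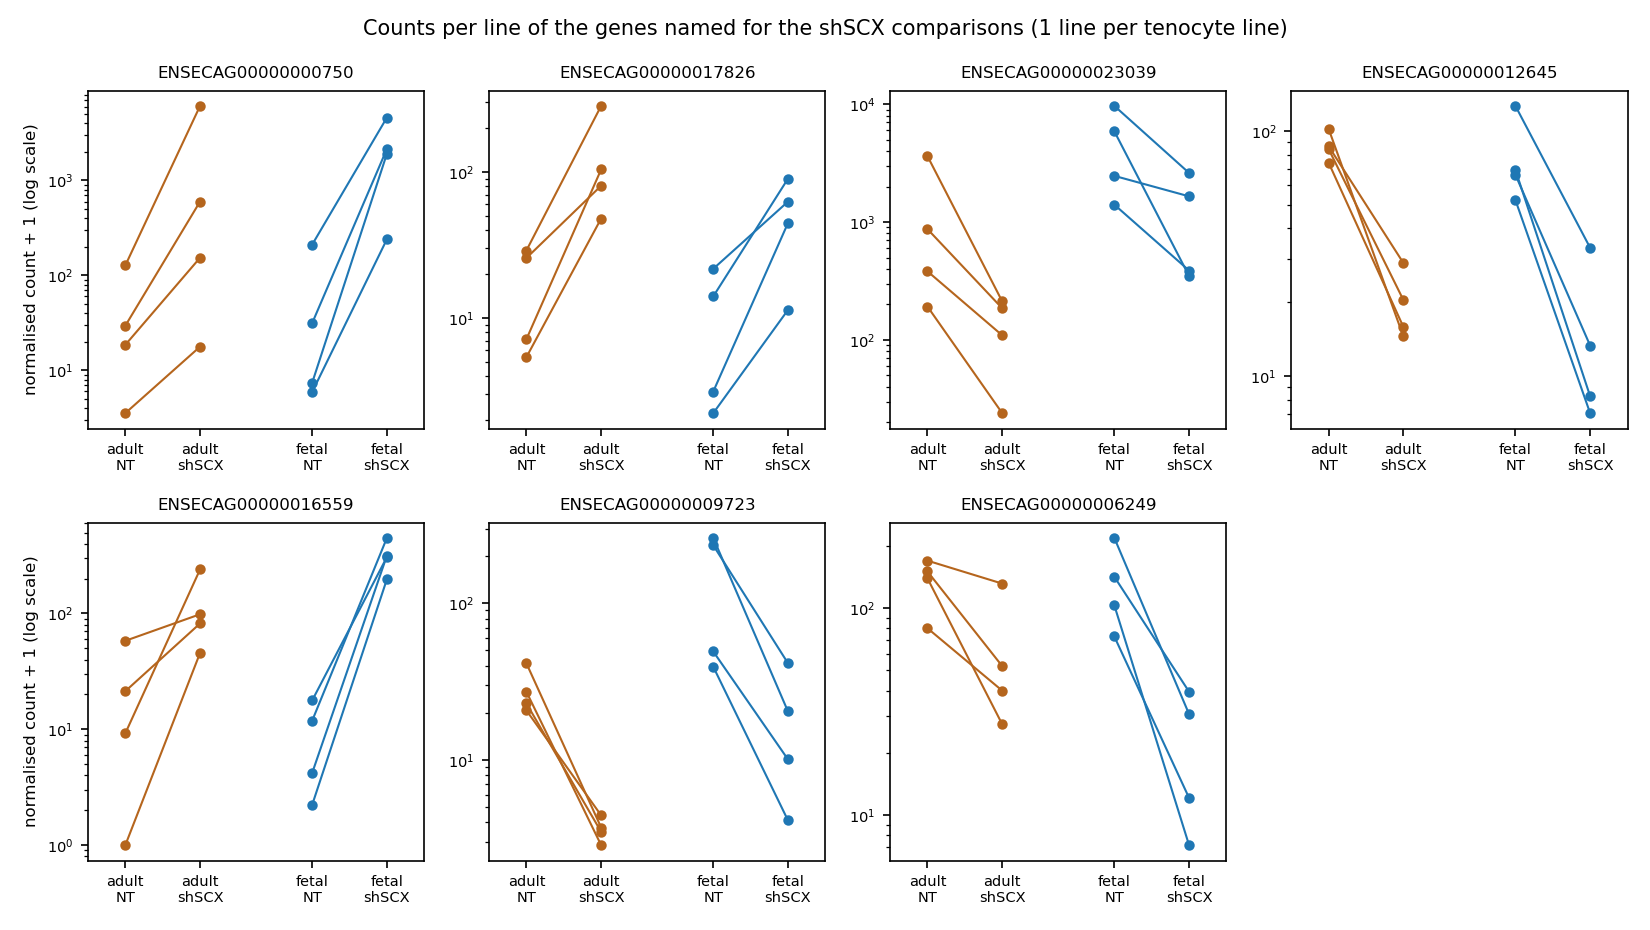
Normalised counts plus 1, on a log scale, of the 7 genes named for the adult and fetal shSCX comparisons; each connected pair of points is one line with its NT and shSCX library, adult in brown and fetal in blue. ENSECAG00000000750 rose in all 8 lines, by 2.05 to 5.57 on the log2 scale in adult lines and by 4.44 to 7.84 in fetal lines.

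At least 2-fold changes were seen in 459 fetal calls, 344 upward and 115 downward, and the median size of a called change was 0.60 on the log2 scale. Before adjustment 4523 genes were at p under 0.05, where 621 would be expected by chance, and 45.2% of tested genes had the same sign in all 4 fetal lines. Without the line as a block 58 genes were called, and among the named genes ENSECAG00000016559 kept its call. The fetal count was 270 without 320d and 789 without 319d. The pair of 316d libraries stood furthest apart: 2002 genes differed at least 2-fold between them, against 649 to 1061 in the other 7 lines, and 1732 genes were called without 316d.

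Falling genes were more frequent among abundant transcripts in fetal lines. Of the 100 genes with the highest mean share of counts, 33 fell and 5 rose in fetal tenocytes, against 1 and 3 in adult tenocytes, and of the 900 genes ranked next 183 fell and 82 rose in fetal tenocytes. Among the 7418 tested genes beyond rank 5000 the order was the other way, with 610 rising and 366 falling. The median log2 ratio of the 100 most abundant genes was -0.27 ± 0.12 over fetal lines and -0.08 ± 0.08 over adult lines (SD, n = 4 each), which was not past the threshold (exact permutation p = 0.0571, Benjamini-Hochberg adjusted 0.0856 over 6 measures compared between stages). With scaling by total counts the fetal value was -0.15. The adult value was not computed with that scaling, so the difference between stages is known with TMM scaling only. The adult median was below 0 in each of the 4 lines, and over all 8 lines the exact sign-flip permutation p was 0.00781. In a fit over all 8 lines, 37 of the 100 most abundant genes fell and 12 rose. The median of the 100 most abundant genes was added after seeing the data.

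The genes called with shSCX in adult and in fetal lines went largely the same way at both stages, while over all genes tested at both 62.7% had the same sign. Of the genes tested at both stages, 198 rose in both and 55 fell in both, where independent lists would share 21.9 and 6.63, and 0 were called in opposite directions. ENSECAG00000017826, ENSECAG00000023039 and ENSECAG00000012645, named for adult lines, were also called in fetal lines, with log2 fold changes of 2.56, -2.04 and -2.53. ENSECAG00000009723, named for fetal lines, had a log2 fold change of -3.32 in adult lines (edgeR adjusted p = 0.00841), while ENSECAG00000016559 and ENSECAG00000006249 did not pass there (2.62, edgeR adjusted p = 0.121, and -1.29, edgeR adjusted p = 0.0958). Of 321 adult calls tested in fetal lines 318 had the same sign there, and 78.8% were also called.

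Across 12253 genes, which are not independent replicates, the fold changes of the 2 stages correlated with Pearson r = 0.589 and Spearman rho = 0.424. The adult and fetal fits share no library. Of 2114 fetal calls tested in adult lines 1925 had the same sign there, and 12.0% were called. Over all 2114 the median change in the fetal direction was 0.59 on the log2 scale in fetal lines and 0.26 in adult lines. Over the 321 adult calls the median change in the adult direction was 0.85 in adult lines and 0.88 in fetal lines. Values of a list are raised in the lines that chose it.

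**Figure D2:**
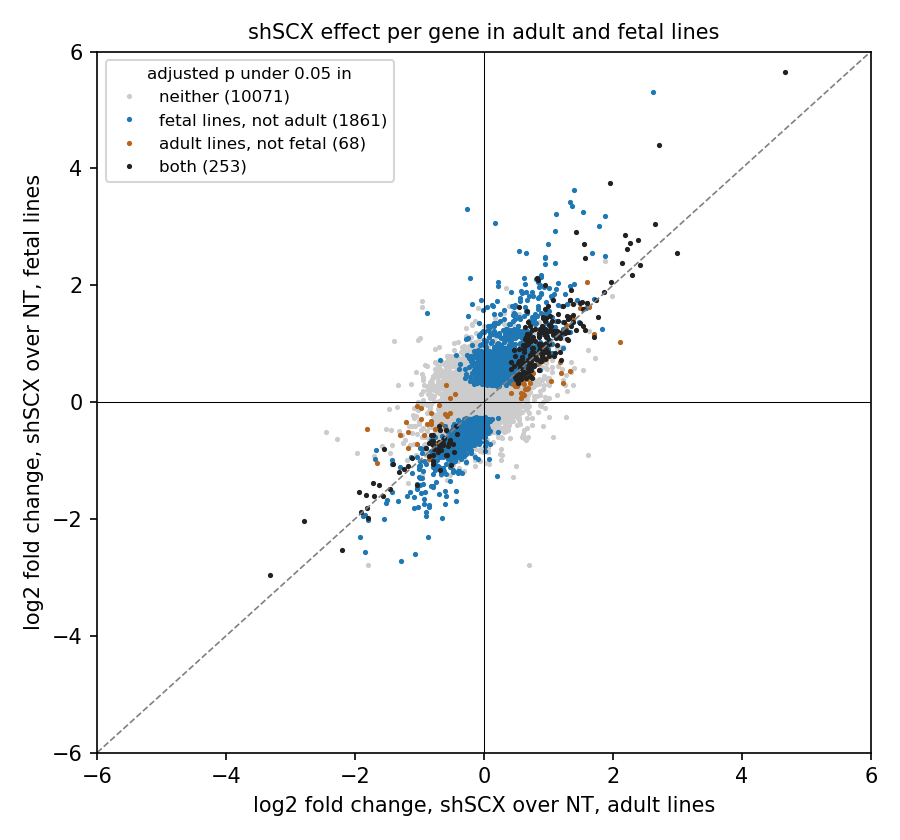
Log2 fold change of shSCX over NT in adult lines (x axis) and fetal lines (y axis), one point per gene tested at both stages, coloured by where the gene was called; the dashed line marks equal change. The 253 genes called at both stages lie in the quadrants of equal sign, and 1861 genes were called in fetal but not in adult lines.

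No gene was found whose shSCX effect differed between the stages in the edgeR interaction test of 12888 genes (0 called, lowest adjusted p = 0.307). At unadjusted p under 0.05 there were 2006 genes, where 644 would be expected by chance. With a line left out this count ran from 1122 (without 316d) to 2858 (without 271d). With limma voom 0 genes were called and with the DESeq2 Wald test 38. Of these 38, 35 had the more positive log2 fold change in fetal lines. Genes are named here only where the log2 ratios of adult and fetal lines did not overlap. Of these, ENSECAG00000025148 had the smallest p. Its log2 ratios were -2.85 to -0.44 in the 4 adult lines and 1.13 to 2.34 in the 4 fetal lines, from counts of 0 to 70 (log2 difference fetal minus adult 4.76, SE 0.69, edgeR adjusted p = 0.307). Its count of 70 was in the NT library of TB180412, and without that line the difference was 3.88 (edgeR adjusted p = 0.496). ENSECAG00000024578 had log2 ratios of -0.36 to 0.12 in adult lines and 0.94 to 1.69 in fetal lines (difference 1.41, SE 0.23, edgeR adjusted p = 0.307). ENSECAG00000014477 and ENSECAG00000016937 had positive ratios in 4 of 4 adult lines and negative ratios in 4 of 4 fetal lines, with differences of -0.49 (SE 0.10) and -0.50 (SE 0.11), both at edgeR adjusted p = 0.307. With DESeq2, ENSECAG00000024578, ENSECAG00000014477 and ENSECAG00000016937 passed, at adjusted p = 0.00281, 0.0133 and 0.0428. The paired structure is part of this test; without the block 0 genes were called and 39 were at unadjusted p under 0.05.

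The size of the response was compared between stages in a measure added after seeing the data. For each line, genes called by edgeR in the other 7 lines were taken, and their mean log2 ratio in the direction of those lines was computed in the line left out. It was 0.427 ± 0.082 in adult lines and 0.718 ± 0.086 in fetal lines (SD, n = 4 each), and the highest adult line (0.512) lay below the lowest fetal line (0.602). The difference of 0.291 gave an exact permutation p = 0.0286, the smallest that 4 against 4 lines allow, and a Benjamini-Hochberg adjusted value of 0.0856 over 6 measures. Several of these measures were close versions of the median change of abundant genes, each at exact permutation p = 0.0571. This overlap lowers the adjusted value. Without the score of TB180412, and with the lists of the other lines unchanged, the difference was 0.255 (exact permutation p = 0.0571). The lists differed in length, from 2003 to 2629 genes for adult and from 1489 to 2039 for fetal lines, and the longest list went with the lowest score and the shortest with the highest. With lists of one length, the 1000 genes with the smallest p in the other 7 lines, the response was 0.567 ± 0.094 in adult and 0.837 ± 0.092 in fetal lines (SD, n = 4 each; difference 0.270, exact permutation p = 0.0286).

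**Figure D3:**
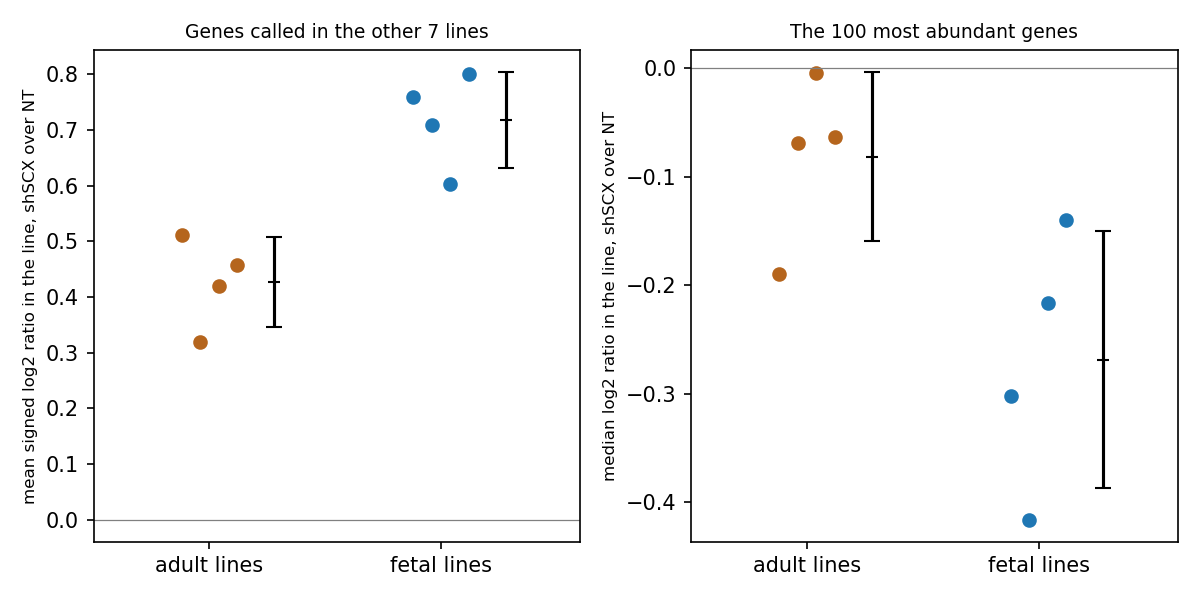
Left, mean log2 ratio of shSCX over NT, signed by the direction in the other 7 lines, of genes called in those lines; right, median log2 ratio of the 100 most abundant genes; each point is one line, and bars are the mean and SD of 4 lines. In the left panel the fetal lines lie between 0.602 and 0.802 and the adult lines between 0.319 and 0.512; in the right panel the stages overlap.

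A single effect of shSCX over all 8 lines, also added after seeing the data, was found for 2450 of 12888 genes, 1192 rising and 1258 falling, with edgeR and the line as a block. Of these, 753 rose and 744 fell with the same sign in 8 of 8 lines. Called genes with the largest changes under the same rule were ENSECAG00000000750 (log2 fold change 5.21, SE 0.40, edgeR adjusted p = 1.74e-05) and ENSECAG00000016559 (3.93, SE 0.60, edgeR adjusted p = 0.00153) upward. Downward they were ENSECAG00000009723 (-3.09, SE 0.22, edgeR adjusted p = 1.07e-05) and ENSECAG00000023039 (-2.40, SE 0.37, edgeR adjusted p = 0.00164). At least 2-fold changes were seen in 385 genes. Without the block 298 genes were called, and without 320d, with the block, 1497.

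Between fetal and adult NT tenocytes 1 of 12384 genes differed. ENSECAG00000024388 had 59 to 66 counts in the adult NT libraries and 0 to 1 in the fetal NT libraries, an adult to fetal ratio of 217 (95% exact counting interval 38.5 to 8588, edgeR adjusted p = 0.0121). Its counts in the shSCX libraries were 87 to 124 in adult and 2 to 4 in fetal lines, and over all 8 lines it rose with shSCX by 0.88 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0423), in 8 of 8 lines. ENSECAG00000018067 had 13 to 230 counts in adult and 0 to 3 in fetal NT libraries and was not past the threshold (edgeR adjusted p = 0.520). Higher in fetal NT libraries, also not past the threshold, were ENSECAG00000033730, at 883 ± 255 against 137 ± 52.7 normalised counts (SD, n = 4; edgeR adjusted p = 0.0824), and ENSECAG00000023734, at 94.0 ± 25.6 against 11.6 ± 7.71 (SD, n = 4; edgeR adjusted p = 0.520).

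Before adjustment 348 genes were at p under 0.05 between the stages, fewer than the 619 expected by chance. This depended on the lines: the count was 875 without 271d and 704 without TB171012. It was 245 to 377 with any other line left out. The DESeq2 Wald test called 22 genes and limma voom 1. With DESeq2 the genes ENSECAG00000018067 (adjusted p = 5.74e-07), ENSECAG00000033730 (3.67e-11) and ENSECAG00000023734 (4.39e-06) passed. With edgeR, ENSECAG00000018067 passed without TB171012 (adjusted p = 0.0291) and ENSECAG00000033730 with no filter on low counts (adjusted p = 0.0452). The call of ENSECAG00000024388 was lost without TB180412, TB130911, S, 271d, 316d or 320d (edgeR adjusted p 0.0550 to 0.113), and without TB171012 3 genes were called. The biological coefficient of variation between NT lines of a stage was 0.347, against 0.159 and 0.154 in the paired adult and fetal fits.

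**Figure D4:**
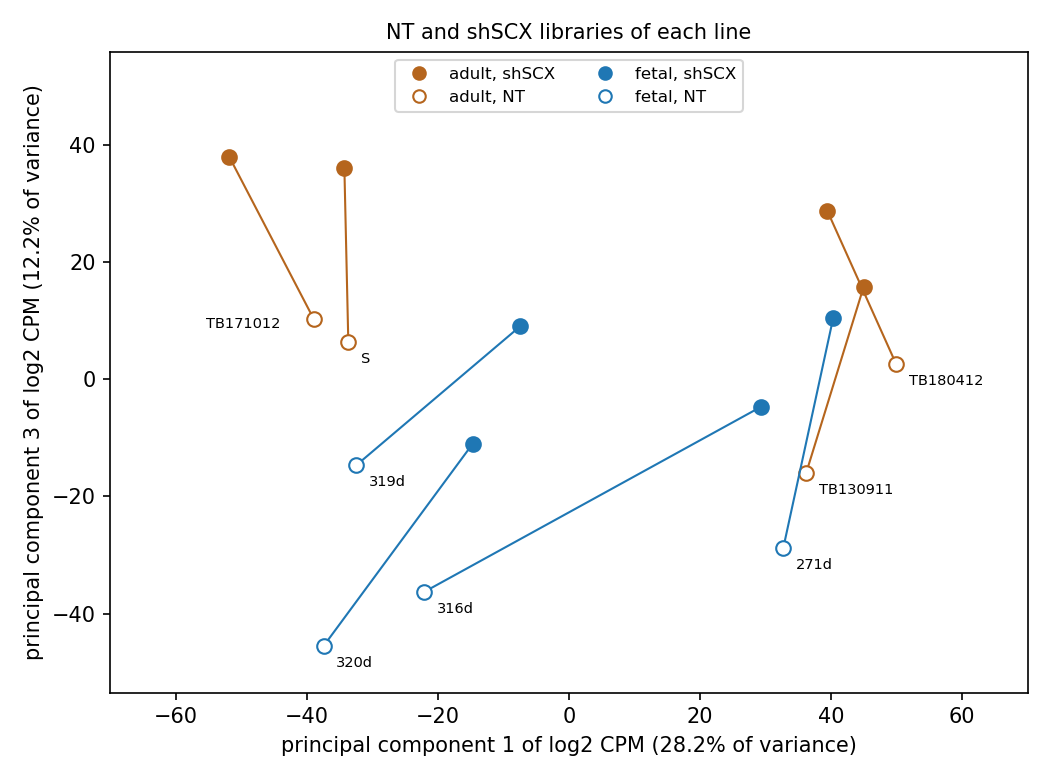
Principal components 1 and 3 of log2 CPM over 12888 genes; open circles are NT and filled circles shSCX libraries, joined within a line, adult in brown and fetal in blue. Along component 3 (12.2% of variance) the shSCX library lies above its NT library in 8 of 8 lines, by 23.8 to 39.2; component 1 (28.2%) parts lines of both stages.

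Component 1 of the libraries, with 28.2% of the variance of log2 CPM, had both libraries of TB171012 and S and the NT libraries of 319d (-32.5) and 320d (-37.4) at one end, and both libraries of TB180412, TB130911 and 271d at the other. Moves from the NT to the shSCX library were compared on 4 components after seeing the data. They went one way in 8 of 8 lines on components 3 and 4 (exact sign-flip permutation p = 0.00781 each, the smallest that 8 lines allow, Benjamini-Hochberg adjusted 0.0156). On components 1 and 2 they did not (exact sign-flip permutation p = 0.188 and 0.156). Along component 1 the shSCX library moved up from its NT library in 4 of 4 fetal lines, by 51.5 in 316d, 25.1 in 319d, 22.7 in 320d and 7.61 in 271d. Among adult lines it moved by 8.76 in TB130911 and by -0.593, -10.6 and -12.9 in S, TB180412 and TB171012.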

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

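The response measure, the depth comparison and the lists of one stage in this part were chosen after the shSCX results were seen.

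Outlying libraries were sought in 108 groups of 4 values with Dixon's ratio at its 95% critical value, where chance gives about 1 in 20 groups; 2 were found, both for ENSECAG00000024388. In adult NT libraries line S was highest at 1.77 log2 CPM, and in fetal NT libraries 271d was highest at -2.81 log2 CPM, which is a count of 1 where the other fetal NT libraries had 0.

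ENSECAG00000025148, ENSECAG00000014477 and ENSECAG00000016937 moved one way in all 4 adult lines and the other way in all 4 fetal lines, with log2 differences fetal minus adult of 4.76, -0.49 and -0.50. The edgeR interaction test did not call them (adjusted p = 0.307 each). They were picked for small p among those of 12888 genes whose log2 ratios did not overlap between the stages. Opposite signs among them therefore carry little weight.

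The response of genes called in the other 7 lines was larger in fetal lines by 0.291, with no overlap between stages, and goes with the larger number of fetal calls (2138 against 325). Lower depth of the adult libraries is argued against, since their median total count was 1.15 times the fetal one. A larger spread of log2 ratios between adult lines stays open: the adult to fetal ratio of the median gene-wise SD was 1.04, and ran from 0.902 to 1.25 as lines were left out. A stronger shSCX response in fetal lines is consistent with the exact permutation p = 0.0286, and remains a hypothesis because the adjusted value was 0.0856 and because the depth of SCX knockdown per stage was not analysed here. Lists chosen in one stage went the same way: genes called in 3 adult lines averaged 1.10 in the adult line left out and 1.33 in fetal lines, and genes called in 3 fetal lines averaged 0.896 in the fetal line left out and 0.561 in adult lines.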

How the results depend on the processing

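The fit over 8 lines, the response score, the abundant-gene median and the surrogate variable were chosen after seeing the data. Without the replicate block, and so without the pairing by line, 1 adult, 58 fetal and 298 8-line genes were called, since differences between lines then enter the error; the interaction stayed at 0 and the correlation of stages at 0.599. The DESeq2 Wald test called 709 adult genes, 38 for the interaction and 22 between stages; the cause was not tested. At adjusted p 0.10 there were 566 adult, 3574 fetal and 2 stage calls, and with a fold of at least 2, 117 adult, 459 fetal and 385 8-line calls, as a looser or tighter threshold gives by construction. No filter gave 2 stage calls, and all 16 libraries in one fit 508 adult calls; the cause was not tested. With each line left out, there were 27 (without S) to 237 adult calls and 270 (without 320d) to 2221 fetal calls. Between stages there were 0 to 3, and in the 8-line fit 1497 (without 320d) to 2636. The interaction stayed at 0 and the correlation ran from 0.492 to 0.672. With the score of 1 line left out and the lists unchanged, the response difference ran from 0.255 (without TB180412, exact permutation p = 0.0571) to 0.330. The median of the 100 most abundant genes in fetal lines ran from -0.15 (total counts) to -0.31 over its alternatives.

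DESeq2 size factors, limma voom and the stricter filter kept every count of calls within 1.5 times the edgeR count, and size factors moved no median log2 fold change by more than 0.0149. No named gene reversed direction in any fit: 178 fold changes kept their side of the threshold, 18 lost their call (11 with a line left out, 7 without the block) and 8 gained one (6 with DESeq2). The 178 include ENSECAG00000025148 in the DESeq2 interaction test, which gave this gene no adjusted p. Depth limits the ratio of ENSECAG00000024388, which rests on 1 count in the fetal NT libraries. Other settings for the gene lists (estimated correlation, fry, no block) and for SCX expression were not run, because the identifiers carried no symbols.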

Other observations

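The tests that split the libraries for the adult, fetal and interaction counts, the marker test of 316d and the comparison of NT lines on shSCX genes were chosen after the results were seen.

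Other splits of the libraries were fitted. For adult and for fetal lines only 8 splits part all 4 pairs, too few for a share under 0.05; the real split was the 1 with the most calls each time (325 and 2138), and the highest other gave 0. The remaining splits of the 35 part 2 or 0 pairs, so they are not the same paired comparison and decide nothing about chance. Over all 35, 1 gave as many fetal calls as there were (the real one; highest other 5) and 2 gave as many adult calls. The other adult split set both libraries of TB171012 and S against those of TB180412 and TB130911 and called 5196 genes. It parts lines and not hairpins. Splits that part 0 pairs were fitted without the line as a block, so both libraries of a line counted as replicates. The 5196 calls therefore compare 2 lines with 2 lines, and their number is inflated. Over all 8 lines, 1 of 100 drawn splits gave as many as the real 2450 (highest other 60). That is the lowest share that 100 draws allow, and it argues against chance there.

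For the stages chance cannot be excluded. In the interaction 2 of 35 splits of the lines gave at least the 2006 genes at unadjusted p under 0.05 (highest other 3029). The real count of 0 called genes is reached by 35 of 35 splits by construction (highest other 1) and decides nothing. Between NT libraries 6 of 35 splits gave at least 1 gene, and the highest other, 312 genes, set TB171012, S, 319d and 320d against TB180412, TB130911, 271d and 316d. These sets mix stages, and passages 7 and 8 occur in both; no label used here names what they share.

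The shSCX library of 316d lay far from its NT library (r = 0.958 over 12888 genes) and correlated more with the shSCX library of 271d (0.973). The same held for 271d, whose shSCX library correlated 0.970 with its own NT library. This is the same correlation seen from the other end, so it does not tell whether 316d or 271d stands out. The shSCX libraries of 316d and 271d also had the lowest chi-square per degree of freedom (43.3) of 24 pairs within groups. A mislabelled library cannot be told apart: over 17 genes on (4 CPM or more) or off (0.3 CPM or less) in each NT library it had 0 mismatches with 316d NT and 1 with the nearest other line, but the pairs of TB171012 and 320d also had 1 each. Deviations from the group mean correlated 0.41 with 316d NT and at most 0.188 with another fetal line, against up to 0.371 between different adult lines. A mixture with another line also stays open: the 11 genes on in TB171012 and off in 316d NT stood at a median of 0.901% of the TB171012 level, but no such genes were found for the other fetal lines. No biological explanation was tested, since the labels give none for this line.

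Abundant genes were lower in fetal shSCX libraries. Scaling is argued against as the source of a gap between abundant and rarer genes. Ranks 1 to 100 lay below genes beyond rank 1000 by -0.28 on the log2 scale (mean of 4 fetal lines, below 0 in each). A scaling factor moves both alike. The level of the abundant genes does depend on scaling: the fetal median was -0.27 with TMM and -0.15 with total counts. The gap alone does not tell whether abundant genes fell or rarer genes rose. The 10 most abundant genes alone are argued against too, since ranks 11 to 100 lay lower by -0.27. In adult lines the median log2 ratio of the 100 most abundant genes was below 0 in each line, from -0.19 to -0.005. Over all 8 lines its exact sign-flip permutation p was 0.00781, the smallest that 8 lines allow. Relative to genes beyond rank 1000, adult lines ran from -0.19 to 0.003, and the exact sign-flip permutation p over all 8 lines was 0.0156. Whether adult lines share the change to the same extent stays open, at exact permutation p = 0.0571 between stages. Which genes these are was not analysed here, so no biological explanation beyond stage was tested.

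On principal component 3 the adult NT libraries lay mostly towards the shSCX side of the fetal NT libraries, with an overlap of TB130911 (-15.99) and 319d (-14.71). The hypothesis that genes moved by shSCX already differ between the stages was tested on pairs of an adult and a fetal NT library, with genes called in the other 6 lines. The adult library lay on the shSCX side in 12 of 16 pairs, by a mean of 0.141 on the log2 scale, with exact permutation p = 0.257 over 70 labelings, so the test left the hypothesis open.

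Of 17 genes on (4 CPM or more) or off (0.3 CPM or less) in each NT library, 0 separated adult from fetal lines. Among them 11 were on in TB171012 alone. The cutoff left out ENSECAG00000024388, which did separate the stages but reached at most 1.77 log2 CPM in adult NT libraries. The 17 genes therefore do not tell whether genes expressed at lower levels follow stage.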
